A study of Mus musculus with 10 samples.

How the data were processed

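RNA-seq libraries of mouse B cells were compared between mice with a B cell knockout of Pcbp1 (floxed Pcbp1 with Mb1-Cre, KO) and control mice (WT). The 10 libraries were naive splenic B cells on day 0 (2 WT, 2 KO) and induced germinal center B cells on day 4 (3 WT, 3 KO). Induced germinal center B cells, called iGCB, are B cells grown on 40-LB feeders, fibroblasts that present CD40 ligand and BAFF. The labels describe total RNA and an mRNA library kit. They do not give the sex, age or strain of the mice, whether WT mice carried Cre, or whether each library came from a separate animal, so p-values measure only the spread between these libraries.

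The deposited values were counts per gene symbol, which the authors made with featureCounts on the mm10 genome build per the submitters' processing notes. The aligner, the annotation, the tool versions and the strand setting are not given in the sources used here. The values were whole numbers over 55492 symbols, of which 24219 were 0 in every library, and no column lacked a sample. Among counts from 1 to 20, odd values made up 17.7% to 26.9% of a library's values, as when both mates of a read pair are counted singly, so a count is not a count of independent fragments. Positions and gene types came from the GENCODE M21 annotation of mm10, which held 53292 (96%) of the symbols.

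Each library held 33400672 to 63576147 counts. A gene at 0 counts over a group was given a bound of 3 counts over the group's summed counts, used only in list medians. These bounds take counts as independent, which mates counted singly are not, so no fold is given against a group at 0, apart from 1 fitted difference for Zfp521 that is marked as depending on the prior count.

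Genes with too few counts were left out with edgeR's filterByExpr by group (minimum count 10), which kept 21010 genes. Counts were scaled with TMM factors and fitted in 1 quasi-likelihood negative binomial model over the 4 groups with 6 residual degrees of freedom (edgeR 4.0.16 in R 4.3.3). Contrasts were KO against WT in naive cells, KO against WT in iGCB cells, iGCB against naive in WT cells, and the difference of the KO effects between stages. All tests were two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. Fold changes are on the log2 scale with their standard errors (SE), computed as the absolute fold change over the square root of the F statistic. Expression levels are in CPM, computed by edgeR on the TMM-scaled totals, as mean ± SD.

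Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 3 measured members. There were 44 lists with 965 genes, of which 3 had no symbol in the table. They cover metabolic and stress pathways, B cell states, markers of other cell types and checks, and 43 were tested. The adjusted p of camera with a correlation estimated per list is given beside the calls, and fry was a further alternative. With an estimated correlation 0 lists were called in any of the 4 comparisons.

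Before the data were examined, the comparisons, the tests, the gene lists, a rule for the genes named and most alternatives were fixed. The rule took Pcbp1 and Pcbp2 in every comparison. It took the 8 higher and the 8 lower genes with the largest fold change among those past the threshold with a mean of at least 2 on the log2 CPM scale and groups that did not overlap, without V, D and J segments, predicted genes and clone names. For each list it took up to 4 members past the threshold with the largest fold change, or the members with the smallest p where none passed, and for other cell types the 4 most abundant members. Other genes are named as chosen after their values were seen. The results of some genes that the rule takes are not reported here.

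The labels number the libraries and the series text speaks of pairs, without saying what a pair shares. After group means were removed, naive WT and KO libraries with the same number correlated at 0.60 across 8944 genes. In iGCB cells the same-number correlations were 0.50, -0.15 and 0.01. The main fit therefore used no pairs, and the numbers entered only the replicate block among the alternatives. For KO against WT and the difference of KO effects, that block joined libraries of one number within a stage. For iGCB against naive it joined libraries of one number within a genotype, where the WT correlations were -0.13 and 0.15. Xist and Y-linked genes showed that naive WT 1 and naive KO 1 were from female mice and the other 8 libraries from male mice, so naive values are also given within the female and the male pair. Naive WT 1 and iGCB WT 1, which the replicate block joins for iGCB against naive, therefore cannot come from 1 animal.

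The pipeline was tested on simulated data before use. In a simulation with 3 against 3 libraries, 57.3% of genes changed by 2-fold and 85% of those changed by 4-fold were recovered, with 4.2% of calls false. With 2 against 2 libraries as in the naive comparison, 17% at 2-fold and 72% at 4-fold were recovered, with 5.3% of calls false. The simulation drew all libraries from the same dispersion trend, without a sex effect, and fitted the 4 groups together. The real naive libraries were less alike than the iGCB libraries and of mixed sex, so these shares may not hold for the naive comparison.

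Alternatives tried were DESeq2 1.42.0, RLE factors, library size without TMM factors, no low-count filter, a minimum count of 50, a replicate block, limma-voom, fits of only the groups compared, a fold threshold, leaving out immunoglobulin and mitochondrially encoded genes, and leaving out each library in turn. After the data were seen, a sex term, a fit without the 2 female naive libraries, counts divided by 2, counts thinned to the smallest library, and DESeq2 on only the groups compared were added. Transcript GC content and length were computed with Biostrings 2.70.1, and figures were drawn with matplotlib 3.10.9. The H2-Q genes are close paralogs whose reads can be shared, and how multi-mapped reads were counted is not given. The antisense transcript 1600020E01Rik overlaps Pcbp1 at its start, so without a known strand setting its counts can include Pcbp1 reads. Data on protein, mitochondrial function or antibody were not analysed here.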

Results

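Gene expression was measured by RNA-seq in splenic naive B cells on day 0 and in iGCB cells on day 4 of culture, from WT mice and from mice whose B cells lack Pcbp1, an RNA-binding protein that recognises cytosine-rich sequences and also carries iron. The 4 groups were naive WT (2 libraries), naive KO (2), iGCB WT (3) and iGCB KO (3). Total counts were 63576147 and 39625752 in naive WT, 58983878 and 41316698 in naive KO, 33400672, 36497329 and 41824901 in iGCB WT, and 35109868, 33568105 and 33974737 in iGCB KO. The first principal component separated naive from iGCB libraries and held 85.1% of the variance among expressed genes, against 4.8% for the second. Pearson correlations of log2 CPM within a group were 0.9342 to 0.9383 for naive libraries and 0.9794 to 0.9826 for iGCB libraries. Replicates differed by more than counting error, with a chi-square per degree of freedom of 24.4 to 236 between libraries of a group. The mitochondrial genome gave 3.13% ± 0.42 of counts in naive WT (SD, n = 2), 3.08% ± 0.15 in naive KO (n = 2), 3.66% ± 0.86 in iGCB WT (n = 3) and 4.43% ± 0.35 in iGCB KO (n = 3).

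The comparison of naive KO with naive WT asked what loss of Pcbp1 does to resting B cells. Pcbp1 (ENSMUSG00000051695.6, mm10 chromosome 6, 86524492 to 86526321) went from 118 ± 48.5 CPM in WT (n = 2) to 2.39 ± 2.75 CPM in KO (n = 2), a log2 fold change of -5.59 (SE 0.82), and its adjusted p of 0.0561 missed the threshold. The raw Pcbp1 counts were 9032 and 3327 in WT and 266 and 20 in KO. Pcbp2, its close relative, had a log2 fold change of -0.22 (SE 0.16, adjusted p = 1). Of 7 measured MHC class I genes of the H2-Q cluster on chromosome 17, 4 fell, and H2-Q1, H2-Q2 and H2-Q10, all at low levels, did not pass the threshold. H2-Q7, which encodes the Qa-2 antigen, went from 311 ± 84.4 to 22.4 ± 2.96 CPM, a log2 fold change of -3.80 (SE 0.31, adjusted p = 0.00183). H2-Q6 fell by 2.66 (SE 0.23), H2-Q5 by 2.02 (SE 0.29) and H2-Q4 by 1.23 (SE 0.16) on the log2 scale. These genes are close paralogs, so the division of reads among them is uncertain. Chosen after their values were seen, the class I genes H2-K1 and H2-D1 were more abundant (1309 and 1077 CPM in WT). Their log2 fold changes were -1.29 (SE 0.24, adjusted p = 0.147) and -1.16 (SE 0.23, adjusted p = 0.183), not past the threshold. Cd79a, the signalling chain of the B cell receptor whose locus carries Mb1-Cre in the KO mice, fell from 1280 ± 151 to 423 ± 12.5 CPM, a log2 fold change of -1.60 (SE 0.18, adjusted p = 0.0126).

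In all, 3 genes were higher and 7 lower in naive KO cells, and 1166 of the 21010 genes had an unadjusted p under 0.05. The remaining 5 genes past the threshold were chosen after their values were seen. Jhy was at 0 in both WT libraries and at 31.7 ± 0.331 CPM in KO (adjusted p = 0.00761). Rundc3a rose from 1.18 ± 0.212 to 8.27 ± 0.725 CPM (log2 fold change 2.80, SE 0.34), and the predicted gene Gm15459 rose from 9.73 ± 7.23 to 95.9 ± 12 CPM. The transcript 1600020E01Rik, which overlaps Pcbp1 on the other strand (chromosome 6, 86526247 to 86582466), fell from 16.4 ± 5.82 to 0.387 ± 0.42 CPM. Zfp521 was at 0.219 ± 0.0469 CPM in WT and at 0 in KO (adjusted p = 0.0386). In the female and the male pair, the log2 ratios were -5.14 and -7.55 for Pcbp1, -3.92 and -3.63 for H2-Q7, -2.74 and -2.59 for H2-Q6, -1.68 and -1.50 for Cd79a, and 2.72 and 2.91 for Rundc3a. With a sex term the counts were 35 higher and 22 lower, with DESeq2 they were 115 and 65, and without the low-count filter 126 and 116. A fit of the 4 naive libraries alone called 0 genes in either direction with 348 at an unadjusted p under 0.05. Leaving out 1 library gave 13 higher and 11 lower (without WT 1), 17 and 27 (WT 2), 2 and 10 (KO 1), or 11 and 9 (KO 2), with H2-Q7, H2-Q6, Jhy, Rundc3a and 1600020E01Rik past the threshold in each. Gm15459 stayed past it in 3 of the 4 fits (largest adjusted p 0.104), Cd79a (0.0655), H2-Q4 (0.182) and Zfp521 (0.185) in 2, and H2-Q5 (0.184) in 1. Pcbp1 passed it without WT 2 (-5.96), KO 1 (-8.05) or KO 2 (-4.77).

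Of the gene lists, 7 were lower in naive KO cells by camera, and each had an adjusted p of 0.999 with an estimated correlation. The interferon response list had a median log2 fold change of -0.54, with 36 of 39 members below 0 and 0 past the threshold, also when adjusted over the list alone (adjusted p = 1.33e-05). Its members with the smallest p were Irf7, a master regulator of type I interferon (-1.52, SE 0.44), and Rsad2, an antiviral enzyme (-1.82, SE 0.58). The B cell receptor list had a median of -0.19 with 1 of 22 members past the threshold, Cd79a (adjusted p = 0.00801). The naive follicular list had a median of -0.27 with 0 of 22 past the threshold (adjusted p = 0.0256), including Satb1 at -0.77 (SE 0.33) and Foxo1 at -0.45 (SE 0.20). The immediate early list had a median of -0.26 with 0 of 17 past the threshold (adjusted p = 0.0357). Marker lists of other cell types had medians of -0.30 for myeloid (0 of 24 members past the threshold, adjusted p = 0.000541), -0.16 for erythroid and platelet (0 of 14, adjusted p = 0.0196) and -0.71 for fibroblast genes (0 of 29, adjusted p = 0.0256). Naive KO 2 held less RNA of these markers than the other naive libraries. Its summed myeloid markers were at 210 CPM against 903, 795 and 1186, and its erythroid markers at 35.8 CPM against 132, 172 and 247. In the female and the male pair, the list medians were -0.64 and -0.32 for interferon, -0.31 and -0.06 for B cell receptor, -0.23 and -0.19 for naive follicular, -0.38 and -0.21 for immediate early, 0.33 and -2.25 for myeloid, 0.19 and -2.23 for erythroid and 0.00 and -1.61 for fibroblast genes. With library size alone as scaling, the list medians over all naive libraries were -0.41 for interferon, -0.05 for B cell receptor, -0.13 for naive follicular, -0.13 for immediate early, -0.17 for myeloid, -0.04 for erythroid and -0.60 for fibroblast genes. Without WT 2 and without KO 1, 19 and 23 lists were called, without KO 2 camera called 0, and without WT 1 the interferon list turned direction (adjusted p = 1).

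**Figure D1:**
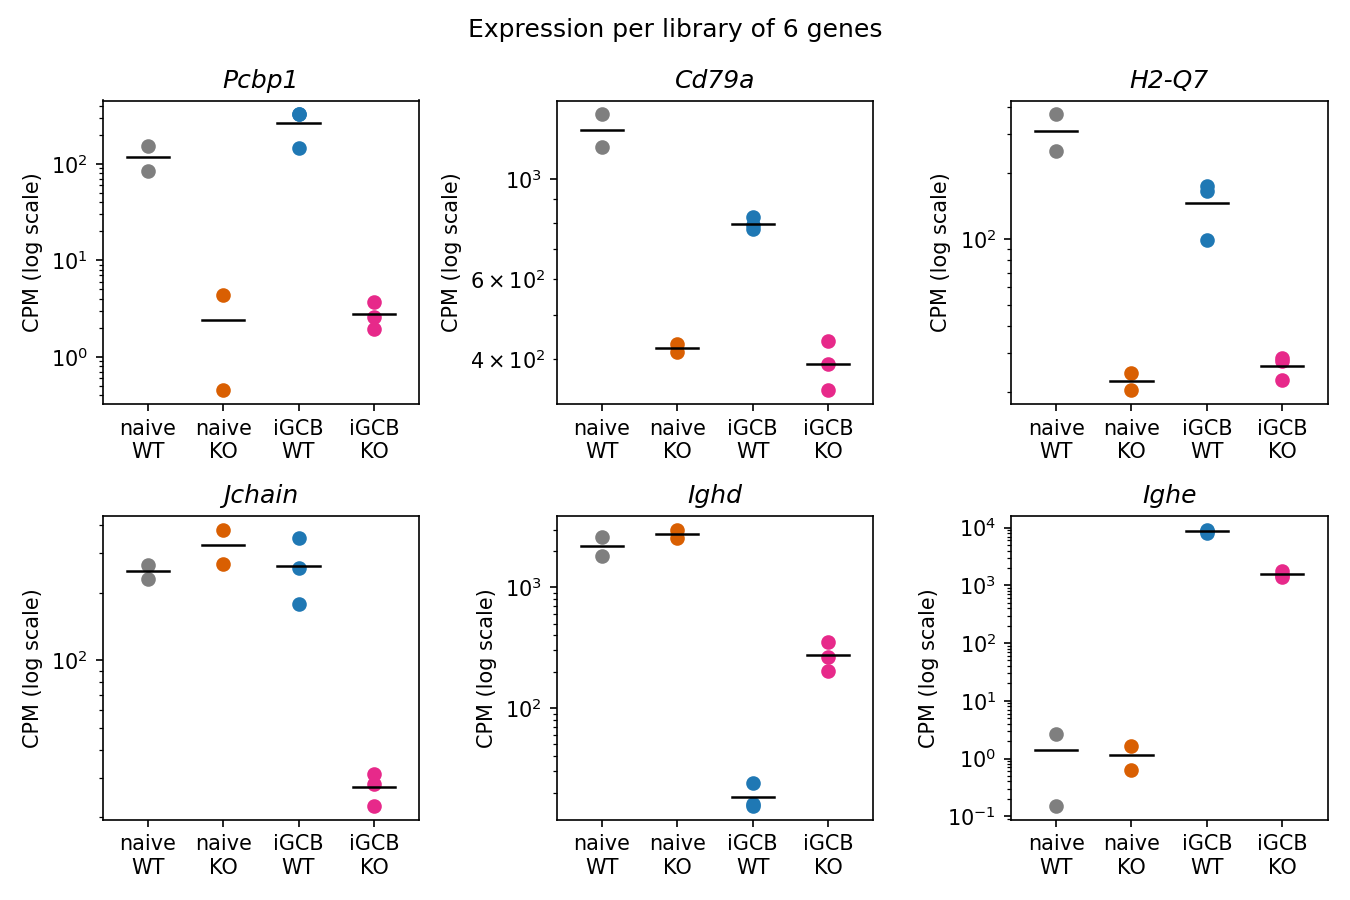
Expression in CPM (log axis) of 6 genes in each library, with 1 point per library and a bar at the group mean, for naive WT (n = 2), naive KO (n = 2), iGCB WT (n = 3) and iGCB KO (n = 3). Pcbp1, Cd79a and H2-Q7 lie lower in KO at both stages, Jchain is at 262 CPM in iGCB WT and 27.2 CPM in iGCB KO, Ighd at 18.5 and 273 CPM, and Ighe at 8660 and 1540 CPM (adjusted p = 0.0590).

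The comparison of iGCB KO with iGCB WT asked what loss of Pcbp1 does during germinal center-like activation. Pcbp1 fell from 267 ± 103 CPM in WT (n = 3) to 2.75 ± 0.884 CPM in KO (n = 3), a log2 fold change of -6.60 (SE 0.71, adjusted p = 0.00151), and Pcbp2 had a log2 fold change of 0.01 (SE 0.13, adjusted p = 1). The genes that fell include 3 used by secretory cells. Jchain, which joins IgM and IgA into polymers, went from 262 ± 86.3 to 27.2 ± 4.38 CPM (log2 fold change -3.27, SE 0.26, adjusted p = 0.000392). Bhlha15, a transcription factor of secretory cells, fell by 3.55 (SE 0.40), and Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum (ER), fell by 3.01 (SE 0.28). The genes that rose include 2 that resting B cells express. Ighd, the IgD constant region, went from 18.5 ± 4.65 to 273 ± 73.9 CPM (log2 fold change 3.88, SE 0.27, adjusted p = 0.000199). Bank1, a scaffold protein of B cell receptor signalling, rose by 2.88 (SE 0.26).

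In total, 72 genes were higher and 194 lower in iGCB KO cells, with 2051 at an unadjusted p under 0.05. The other higher genes named by rule were Rundc3a (2.88, SE 0.28), Klrb1f (2.35, SE 0.40), the mucin Muc3a (2.26, SE 0.45), the short-chain fatty acid receptor Ffar2 (2.07, SE 0.26) and the kinase Dyrk4 (1.96, SE 0.31). In the female and the male naive pair, log2 ratios were 2.33 and 1.51 for Klrb1f and 2.46 and 1.93 for Muc3a. They were 2.04 and 1.23 for Ffar2 and 2.20 and 2.72 for Dyrk4. None of these passed the threshold in naive cells, where WT means were 0.691 to 4 CPM. The naive ratios were 0.20 and 0.49 for Ighd and 0.26 and 0.14 for Bank1. The other lower genes were Hid1 (-3.38, SE 0.40), Mpzl2 (-2.54, SE 0.40), H2-Q7 (-2.48, SE 0.24) and Galk1, which phosphorylates galactose (-2.40, SE 0.24). Chosen after their values were seen, the predicted gene Gm19585 rose from 9.33 ± 1.68 to 102 ± 13.8 CPM, with the smallest adjusted p of the comparison (4.62e-05), and 1600020E01Rik fell from 15.1 ± 3.75 to 0.157 ± 0.0297 CPM. Also chosen after their values were seen, H2-Q6 (-1.82, SE 0.18), H2-Q5 (-1.67, SE 0.23), H2-Q4 (-0.68, SE 0.13) and H2-D1 (-0.95, SE 0.19) fell, while H2-K1 was at -0.81 (SE 0.19, adjusted p = 0.0795). Cd79a fell from 795 ± 24.7 to 390 ± 48.2 CPM (log2 fold change -1.03, SE 0.15). Without WT 1, 2 or 3 the counts were 52 higher and 103 lower, 39 and 145, or 23 and 73, and without KO 1, 2 or 3 they were 27 and 55, 12 and 30, or 15 and 26. Chac1, Gbp2, Muc3a, Slamf1, Xbp1 and H2-Q4 lost the threshold in each of these 6 fits (largest adjusted p 0.236). Dyrk4 (largest adjusted p 0.0958), Egr1 (0.181), Nedd9 (0.0898) and H2-D1 (0.193) kept it in 1 fit, and Klrb1f (0.0723), Idh2 (0.0898) and Neil1 (0.126) in 2. Mpzl2 (0.0943) and Prdm1 (0.104) kept it in 3 fits, Cd79a (0.0714), S1pr1 (0.0778) and H2-Q5 (0.0621) in 4, and Creld2 (0.0664), Hsp90b1 (0.0505) and Lck (0.053) in 5. DESeq2 gave 321 higher and 502 lower, the replicate block 212 and 377, and a fit of the 6 iGCB libraries alone 329 and 534.

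The ER folding and secretion list was lower in iGCB KO cells. All 31 measured members were below 0, with a median log2 fold change of -0.81, and 13 fell past the threshold, or 24 when adjusted over the list alone. Examples are Creld2, an ER stress protein (-1.79, SE 0.24), the ER chaperones Hsp90b1 (-1.56, SE 0.20) and Hyou1 (-1.51, SE 0.19), and Edem1, which sends misfolded proteins to degradation (-1.38, SE 0.14). The camera adjusted p was 6.46e-24, and the adjusted p was 0.222 with an estimated correlation. The plasma cell list, which shares 5 members with the ER list, had 4 of 25 members lower past the threshold, 14 when adjusted over the list alone, and 0 higher. Its lower members were Jchain, Creld2, Prdm1, which encodes the plasma cell regulator Blimp-1 (49.3 ± 22.4 to 10.1 ± 2.68 CPM, log2 fold change -2.28, SE 0.37), and Xbp1, the transcription factor of the unfolded protein response (1180 ± 79.5 to 620 ± 48.4 CPM, log2 fold change -0.93, SE 0.18). Its median was -0.92, or -0.83 with absent members at their bound, and its adjusted p was 1.09e-11, or 0.163 with an estimated correlation. The naive follicular list was higher with a median of 0.38 (adjusted p = 0.000294, and adjusted p = 0.222 with an estimated correlation). Of its 22 members, 2 rose, among them Ighd, and S1pr1, the receptor for lymphocyte egress, fell by 2.14 (SE 0.31). Adjusted over the list alone, 5 rose and 1 fell.

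**Figure D2:**
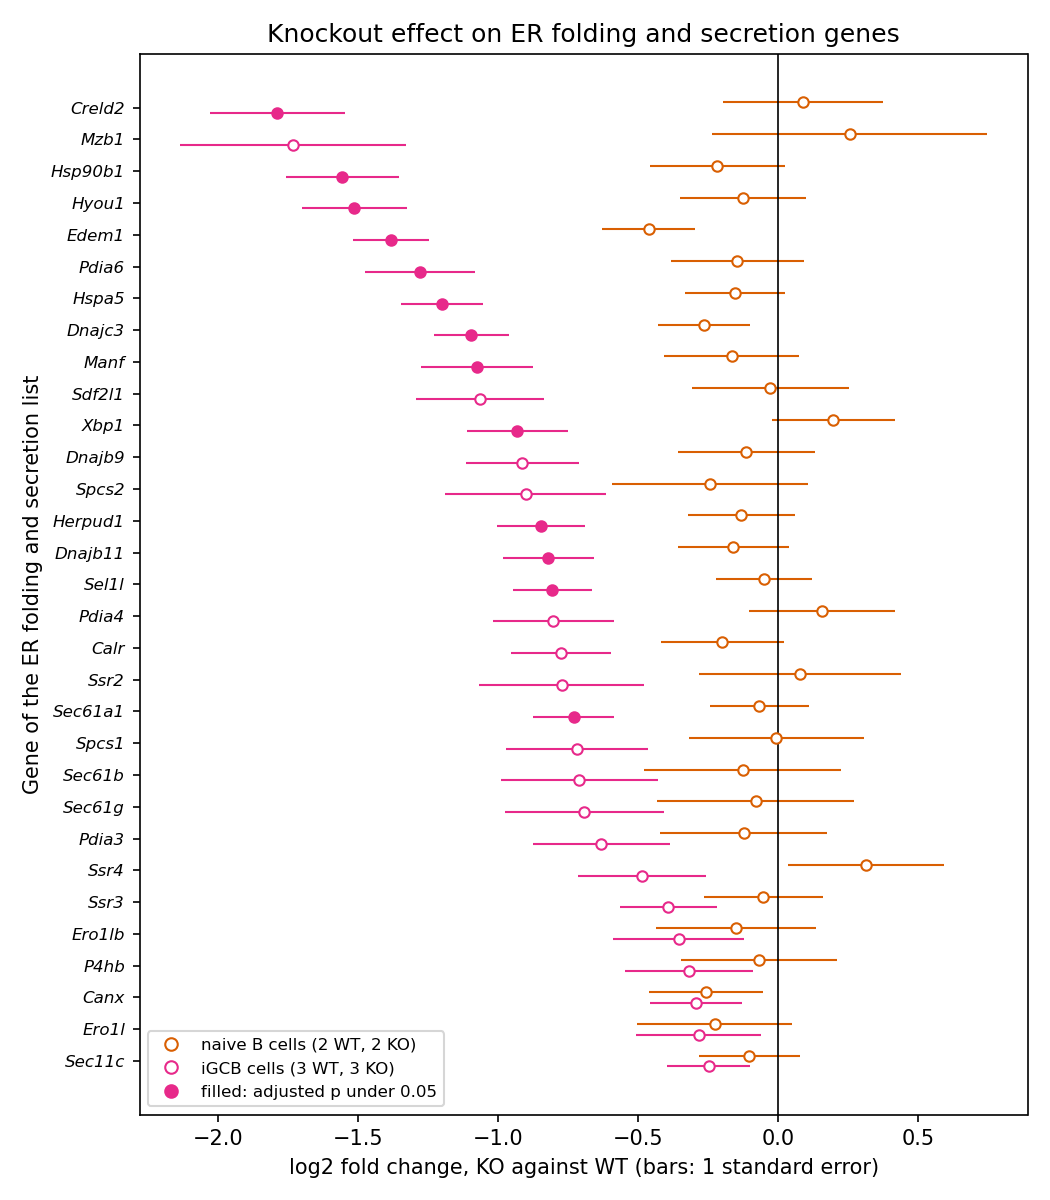
Log2 fold change of KO against WT (points) with 1 SE on either side (bars) for the 31 genes of the ER folding and secretion list, in naive cells (2 WT, 2 KO) and iGCB cells (3 WT, 3 KO), with filled points at an adjusted p under 0.05. In iGCB cells all 31 genes lie below 0 and 13 are filled, and in naive cells 0 are filled and the median is -0.12 (0.02 with library size only).

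Immunoglobulin transcripts also differed between iGCB KO and WT. Of the 194 lower genes, 96 were V, D or J segments of antigen receptor genes (96 of 267 tested), among them 62 of 118 heavy chain V segments (median log2 fold change -1.96), 31 of 115 kappa V segments (median -1.69) and 2 of 3 lambda V segments. These segments made up 0.71% ± 0.26 of counts in iGCB WT and 0.21% ± 0.02 in iGCB KO (SD, n = 3 each). Segments are short and alike in sequence, so reads can be shared among them. Among the 12 immunoglobulin constant genes, Ighd rose and the other 11 did not pass the threshold, with 2 higher and 3 lower when adjusted over the list alone. Chosen after their values were seen, Ighe, the IgE constant region, was at 8660 ± 544 CPM in WT and 1540 ± 185 CPM in KO (log2 fold change -2.49, SE 0.55, adjusted p = 0.0590), and Ighg1 at 2450 ± 295 and 2870 ± 29.8 CPM (0.23, SE 0.50, adjusted p = 0.985). For Ighe the WT libraries (8100 to 9180 CPM) and the KO libraries (1390 to 1750 CPM) did not overlap. The fit shares each gene's spread over the 4 groups, and naive WT libraries held Ighe at 1.42 ± 1.79 CPM. The SE and adjusted p of Ighe therefore also reflect the spread between naive libraries. The class switch and somatic mutation list had a median of -0.16 with 0 of 20 members past the threshold and 2 lower when adjusted over the list alone (adjusted p = 0.0209, and adjusted p = 0.525 with an estimated correlation). The call was lost without WT 3 (adjusted p = 0.138) or KO 1 (0.109). Its members with the smallest p were the DNA end-joining genes Xrcc6 (-0.81, SE 0.20) and Lig4 (-1.07, SE 0.28). In the germinal center list, Nedd9 rose (0.85, SE 0.14) and Neil1, a DNA repair glycosylase, fell (-0.91, SE 0.15), and the list was not called (adjusted p = 0.573).

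Proliferation and protein synthesis lists moved by small amounts in iGCB KO cells, with 0 members past the threshold. The S phase list was lower (median -0.29, 33 of 34 members below 0, adjusted p = 7.3e-05, and adjusted p = 0.858 with an estimated correlation), with Pola1 at -0.50 (SE 0.18) and Uhrf1 at -0.68 (SE 0.25). The G2/M list was lower (median -0.28, 31 of 31 members below 0, adjusted p = 0.00728, and adjusted p = 0.934 with an estimated correlation), with Kif20a at -0.63 (SE 0.23). The cytosolic ribosome list was higher (median 0.28, 47 of 50 members above 0, adjusted p = 3.44e-06, and adjusted p = 0.858 with an estimated correlation), with Rps16 at 0.44 (SE 0.17). The list of ATF4 targets of the integrated stress response was lower (median -0.35, 24 of 31 members below 0, adjusted p = 0.00064, and adjusted p = 0.525 with an estimated correlation), and Chac1, which degrades glutathione, fell by 2.41 (SE 0.50). The p53 target list was higher (median 0.24, 0 of 24 past the threshold, adjusted p = 0.0276, and adjusted p = 0.858 with an estimated correlation), as was the apoptosis list (median 0.19, 0 of 21, adjusted p = 0.0483, and adjusted p = 0.858 with an estimated correlation). The latter included the survival genes Bcl2 at 0.61 (SE 0.16) and Bcl2l1 at 0.59 (SE 0.20). The p53 call was lost without WT 3 (adjusted p = 0.376), KO 1 (0.109) or KO 2 (0.058). The apoptosis call was lost without WT 1 (0.0787), WT 3 (0.271), KO 1 (0.0812) or KO 2 (0.116).

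Mitochondrial and iron genes were examined because the series title names mitochondria and Pcbp1 binds iron. The 13 protein-coding genes of the mitochondrial genome were higher as a list in iGCB KO cells (median 0.20, 0 past the threshold, adjusted p = 0.0473, and adjusted p = 0.858 with an estimated correlation), with mt-Cytb at 0.46 (SE 0.17) and mt-Nd6 at 0.69 (SE 0.27). The mitochondrial call was lost without WT 2 (adjusted p = 0.0776), WT 3 (0.104) or KO 3 (0.202). The mitochondrial genome gave 4.4%, 3.86% and 2.71% of counts in iGCB WT 1, 2 and 3. In iGCB KO 1, 2 and 3 it gave 4.33%, 4.14% and 4.82%, so WT 3 lay furthest from the KO libraries. The nuclear subunits of complex I (median -0.16, 0 of 35 past the threshold, adjusted p = 0.748), complexes II to IV (-0.08, 0 of 24, adjusted p = 0.557) and complex V (-0.13, 0 of 15, adjusted p = 0.748) were not called. The mitochondrial ribosome (median 0.01, 0 of 75, adjusted p = 0.899), import and quality control (-0.08, 0 of 28, adjusted p = 0.976), dynamics and mitophagy (0.02, 0 of 19, adjusted p = 0.833) and mtDNA maintenance lists (0.05, 0 of 20, adjusted p = 0.524) were not called either. In the TCA cycle list, Idh2, the mitochondrial isocitrate dehydrogenase, fell from 82.1 ± 7.57 to 41.8 ± 2.34 CPM (log2 fold change -0.98, SE 0.15), and the list itself was not called (adjusted p = 0.184). The iron homeostasis list was not called (median -0.11, mean 0.25, 0 of 16, adjusted p = 0.818), with Tfrc, the transferrin receptor, at -0.52 (SE 0.13, adjusted p = 0.117, and 1 of the 16 lower when adjusted over the list alone). The iron-sulfur and heme list was not called (median -0.04, 0 of 23, adjusted p = 0.976), with the ferredoxin reductase Fdxr at -0.96 (SE 0.28) and the scaffold Iscu at 0.60 (SE 0.20). In naive cells 0 members of these 11 lists passed the threshold, and none of the lists was called (smallest adjusted p 0.229, for the TCA cycle). Adjusted over the list alone, 1 of the 15 complex V genes was lower in naive KO cells (list median -0.18, mean -0.62).

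Signalling and marker lists gave further differences between iGCB KO and WT. The interferon response list was lower (median -0.44, adjusted p = 0.0326, and adjusted p = 0.939 with an estimated correlation), while its member Gbp2, an interferon-induced GTPase, rose by 1.57 (SE 0.32) and the other 38 did not pass the threshold, with 2 higher and 1 lower when adjusted over the list alone. The NF-kB and CD40 list was higher (median 0.16, adjusted p = 0.0209, and adjusted p = 0.525 with an estimated correlation), and of its 23 members the receptor Slamf1 rose by 0.80 (SE 0.17). The B-1 cell list was higher (median 0.27, 0 of 13 past the threshold and 4 higher when adjusted over the list alone, adjusted p = 0.0182, and adjusted p = 0.427 with an estimated correlation), with Zcwpw1 at 0.91 (SE 0.21). The NK cell list was higher (median 1.27, 0 of 10, adjusted p = 0.00187, and adjusted p = 0.525 with an estimated correlation) at low levels, its summed markers being 22.1, 17.0 and 25.1 CPM in WT and 36.7, 28.9 and 42.4 CPM in KO. The interferon call was lost without WT 2 (adjusted p = 0.434) or KO 1 (0.0922). The NF-kB call was lost without WT 1 (0.0816), WT 3 (0.074) or KO 2 (0.0503), and the B-1 call without WT 3 (0.0638). The B cell receptor list was not called (median 0.09, adjusted p = 0.524), with Cd79a the 1 member past the threshold. Lck, a kinase of the T cell list, rose by 1.60 (SE 0.22), and Egr1, an immediate early transcription factor, by 1.53 (SE 0.30), and neither list was called (adjusted p = 0.585 and 0.303). Myeloid markers were not called as a list (median 0.38, 0 of 24 past the threshold, adjusted p = 0.0509), with summed levels of 72.4, 132 and 81.8 CPM in WT and 162, 127 and 168 CPM in KO. Fibroblast markers did not separate the genotypes, with summed markers at 398, 470 and 477 CPM in WT and 367, 359 and 413 CPM in KO (list median -0.07, 0 of 29 past the threshold, adjusted p = 0.833).

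**Figure D3:**
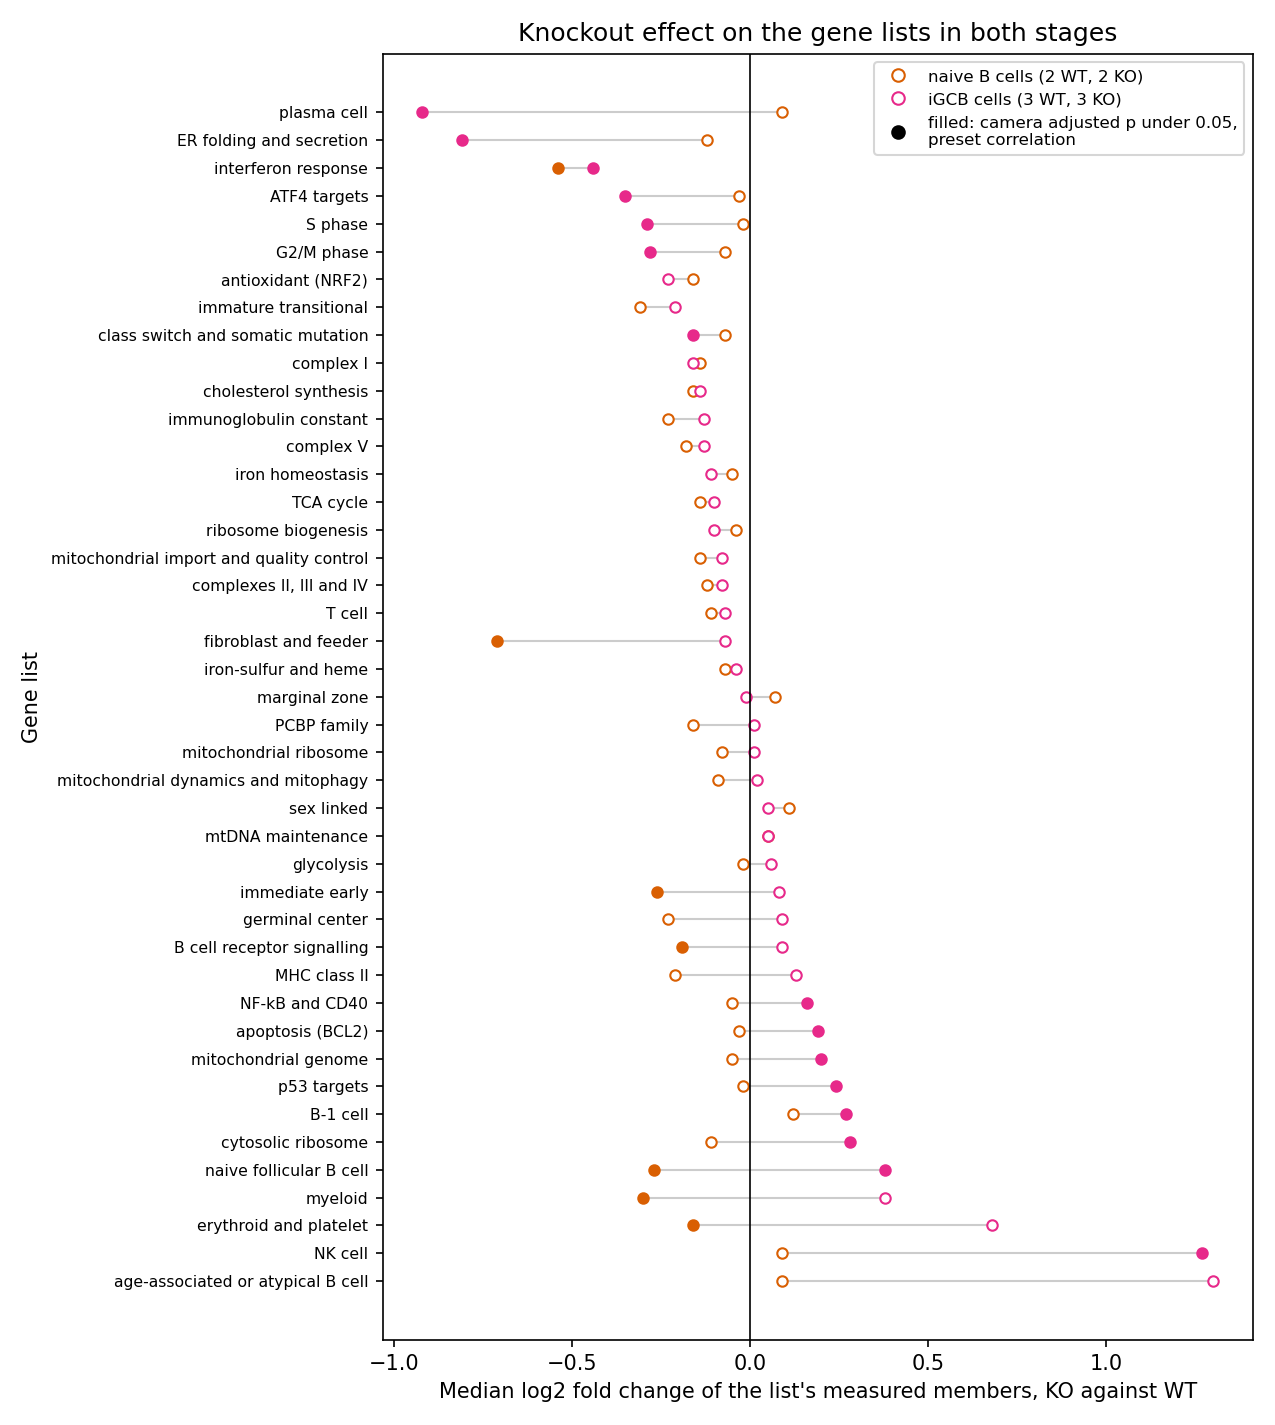
Median log2 fold change of KO against WT over the measured members of each of the 43 tested gene lists, in naive cells (2 WT, 2 KO) and iGCB cells (3 WT, 3 KO), joined by a line, with filled points at a camera adjusted p under 0.05 with the preset correlation. In iGCB cells 15 lists are filled, with medians from -0.92 (plasma cell) to 1.27 (NK cell), in naive cells 7 are filled, all below 0, and with an estimated correlation 0 would be filled in either.

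The comparison of iGCB WT with naive WT describes the culture without the knockout. All naive libraries were from day 0 and all iGCB libraries from day 4. Any difference in library preparation between the days therefore cannot be told apart from an effect of the culture. The proliferation genes rose, with 30 of 31 G2/M genes and 31 of 34 S phase genes higher. Ube2c, which drives exit from mitosis, rose by 5.36 (SE 0.64, 4.79 to 6.36 when 1 library was left out), and Cdk1, the mitotic kinase, from 4.53 ± 2.09 CPM in naive cells (n = 2) to 144 ± 23 CPM in iGCB cells (n = 3). Glycolysis genes rose (17 of 19), with the lactate exporter Slc16a3 at 5.59 (SE 0.34) and Pgk1 at 5.47 (SE 0.29). Of 24 cholesterol synthesis genes 23 rose and 1 fell, with Idi1 at 5.18 (SE 0.19) and Fdps at 4.12 (SE 0.44). In the naive follicular list 18 of 22 genes fell and 4 rose, with the complement receptor Cr2 at -7.45 (SE 0.31) and Ighd at -6.90 (SE 0.32).

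In this comparison 5184 genes were higher and 6661 lower, with 13032 at an unadjusted p under 0.05. Ccn3 was at 0 in both naive libraries and at 167 ± 21.9 CPM in iGCB cells (adjusted p = 1.86e-07). Ighe rose from 1.42 ± 1.79 to 8660 ± 544 CPM, and the chemokine gene Ccl22 from 2.06 ± 0.0887 to 3010 ± 902 CPM. H2-M5 (0.0338 ± 0.0478 to 166 ± 33 CPM), the sodium channel Scn3a (0.101 ± 0.143 to 263 ± 40.6 CPM) and the ATP receptor P2rx3 (0.207 ± 0.114 to 274 ± 81.5 CPM) also rose, from levels too near 0 for a stable fold. Among the lower genes that the naming rule takes are the immediate early factor Fosb (-11.66, SE 0.63), the small nuclear RNA Rn7sk (-9.88, SE 1.17), Rasgef1b (-8.42, SE 0.51), Fos (-8.29, SE 0.54) and Nr4a1 (-8.21, SE 0.25). Rn7sk went from 11000 ± 5230 CPM in naive WT to 11.5 ± 16.1 CPM in iGCB WT. In KO it was at 11800 ± 3790 CPM in naive cells and 2.47 ± 0.797 CPM in iGCB cells. A difference in library preparation between the days could give such a change, and it cannot be told apart from the culture. Leaving out 1 library moved Fosb between -12.27 and -10.9, Rn7sk between -12.26 and -9.29 and Rasgef1b between -9.03 and -7.35, all past the threshold. Pcbp1 had a log2 fold change of 1.18 (SE 0.63, adjusted p = 0.132), or 2.02 with a sex term (SE 0.48, adjusted p = 0.00339), while its relatives Pcbp4 (3.40, SE 0.27) and Pcbp3 (1.59, SE 0.22) rose. Naive WT 1 was from a female mouse and the 3 iGCB WT libraries were male, and without the female naive libraries 5610 genes were higher and 7233 lower.

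By camera, 33 lists were called, 22 higher and 11 lower, and the smallest adjusted p was 0.153 with an estimated correlation. Respiratory chain genes rose, with 31 of 35 in complex I (1 lower), 23 of 24 in complexes II to IV, 12 of 15 in complex V (2 lower) and 7 of 13 of the mitochondrial genome, including Ndufa2 (3.56, SE 0.42) and Cox5a (3.66, SE 0.35). Of 50 cytosolic ribosome genes 41 rose and 2 fell, and of 31 ER genes 29 rose and 2 fell, the higher including Mzb1 (4.01, SE 0.53) and Xbp1 (3.44, SE 0.23). In the germinal center list 13 of 20 rose, including Basp1 (5.08, SE 0.53) and the death receptor Fas (4.65, SE 0.28), and 5 fell, including Rgs13 (9.10 ± 6.88 to 0.0389 ± 0.0674 CPM). Tfrc rose from 80.9 ± 1.55 to 635 ± 48.6 CPM. Of 22 B cell receptor genes 16 fell and 2 rose, the lower including the kinase Syk (-3.94, SE 0.22) and the inhibitory receptor gene Fcgr2b (-3.98, SE 0.31). Of 11 MHC class II genes 9 fell and 1 rose, the lower including Cd74 (-1.52, SE 0.20). Of 39 interferon genes 26 fell, including Ifit3 (-7.03, SE 0.95), and 3 rose. Of 17 immediate early genes 13 fell and 1 rose. Of 24 myeloid markers 21 fell, including Csf1r (-7.00, SE 1.11), and 1 rose. Of 18 T cell markers 14 fell, including Cd4 (-6.26, SE 0.90), and 2 rose. Of 29 fibroblast markers 12 rose, including Col1a1 (5.83, SE 0.63), and 1 fell, in cells grown on fibroblast feeders. Leaving out 1 library moved Mzb1 between 3.34 and 4.42, Basp1 between 4.52 and 6.03, Ifit3 between -7.83 and -5.64, Csf1r between -7.45 and -6.33 and Col1a1 between 5.23 and 6.67, all past the threshold. Without naive WT 1 the interferon (adjusted p = 0.0982), MHC class II (0.112) and B-1 cell (0.134) calls were lost. Without naive WT 2 the PCBP family and TCA cycle calls were lost (0.0523 each), and without iGCB WT 1 the MHC class II call (0.0627).

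The difference of the KO effects between stages asked whether iGCB cells and naive cells respond to the loss of Pcbp1 in different ways. Jchain had a KO effect of -3.27 in iGCB cells and 0.38 in naive cells, the latter not past the threshold (SE 0.29, adjusted p = 1), a difference of -3.65 (SE 0.39, adjusted p = 0.0219). Ighd was at 3.88 in iGCB and 0.32 in naive cells (SE 0.30, adjusted p = 1), a difference of 3.56 (SE 0.40, adjusted p = 0.0219). Sec24d (-3.61, SE 0.42), Fmnl2, a regulator of actin (-2.61, SE 0.34), and Creb3l2, a transcription factor of the secretory pathway (-2.04, SE 0.28), had lower KO effects in iGCB cells. Chosen after their values were seen, Gm19585 (2.38, SE 0.29) had a higher one, and so had Zfp521, at 0 in naive KO (adjusted p = 0.0421). The Pcbp1 effect itself differed by -1.0 (SE 0.91, adjusted p = 0.987). These 3 higher and 4 lower genes were all that passed the threshold, with 1273 at an unadjusted p under 0.05. Without iGCB WT 1, KO 1, KO 2 or KO 3 the counts were 0 higher and 0 lower, without iGCB WT 2 they were 0 and 1, without iGCB WT 3 or naive KO 1 they were 1 and 1, and without naive WT 1, WT 2 or KO 2 they were 12 and 53, 20 and 11, or 6 and 14. DESeq2 gave 65 higher and 173 lower, the sex term 21 and 87, and leaving out immunoglobulin and mitochondrially encoded genes 0 and 0 with 1106 at an unadjusted p under 0.05.

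By camera, 10 lists differed between the stages, 6 higher and 4 lower in iGCB cells, and the smallest adjusted p was 0.114 with an estimated correlation. The ER list had a lower KO effect in iGCB cells (median difference -0.76, all 31 members below 0, 0 past the threshold and 16 when adjusted over the list alone, adjusted p = 2.74e-14, and adjusted p = 0.472 with an estimated correlation). The plasma cell list (median -0.91, 1 of 25 lower, Jchain) had an adjusted p of 3.68e-10, and 0.114 with an estimated correlation. The naive follicular list had a higher KO effect in iGCB cells (median 0.64, 1 of 22 higher, Ighd, adjusted p = 3.42e-07, and adjusted p = 0.114 with an estimated correlation). The KO effects at the 2 stages had a Pearson r of 0.061 and a Spearman rho of 0.108 over 21010 genes, which are not independent replicates. Pearson r was 0.206 over genes with a mean log2 CPM of at least 4 and 0.206 in fits of only the groups compared. It was 0.02 without the female naive libraries and 0.028 without naive KO 1. The genes past the threshold at both stages were Rundc3a, the 1 shared higher gene against 0.0103 for independent sets, and 6 shared lower genes against 0.0646, namely 1600020E01Rik, Cd79a, H2-Q4, H2-Q5, H2-Q6 and H2-Q7. The Cd79a locus carries Mb1-Cre in KO mice, 1600020E01Rik overlaps Pcbp1, and the H2-Q genes may differ by haplotype. Such features of the mouse line would recur at both stages, so the overlap of the 6 lower genes does not show a shared effect of the loss of Pcbp1. They do not cover Rundc3a. Whether its rise comes from the loss of Pcbp1 or from another difference between the mice was not tested. Of the 266 genes past the threshold in iGCB cells, 176 had the same sign in naive cells, 47 of them with an unadjusted p under 0.05 there. Without V, D and J segments these numbers were 119 and 43 of 170. Among all 21010 genes, 1166 had an unadjusted p under 0.05 in naive cells, in either direction.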

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

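The tests of dilution by other cells, of genes matched in GC content and length, of a smaller plasmablast-like share and of reads moved among class I genes were chosen after the results were seen. The results listed here are those whose KO effect differed between iGCB cells (n = 3 per genotype) and naive cells (n = 2 per genotype) in a test of that difference. The genes past the threshold were Jchain (-3.65), Sec24d (-3.61), Fmnl2 (-2.61) and Creb3l2 (-2.04), whose KO effect was lower in iGCB cells, and Ighd (3.56), Gm19585 (2.38) and Zfp521 (6.49), whose KO effect was higher. Zfp521 was at 0 in both naive KO libraries, so its fitted difference depends on the prior count. Each of the 7 genes lost the threshold without at least 1 of the 10 libraries. The lists with a lower effect in iGCB cells were plasma cell (median difference -0.91, adjusted p = 0.114 with an estimated correlation), ER folding and secretion (-0.76, adjusted p = 0.472), ATF4 targets (-0.28, adjusted p = 0.778) and S phase (-0.25, adjusted p = 0.874). Those with a higher effect were naive follicular (0.64, adjusted p = 0.114 with an estimated correlation), cytosolic ribosome (0.42, adjusted p = 0.87), B cell receptor (0.29, adjusted p = 0.524), immediate early (0.62, adjusted p = 0.524), myeloid (1.18, adjusted p = 0.71) and erythroid and platelet (1.61, adjusted p = 0.524). The plasma cell, ER and naive follicular lists were called in every fit without 1 library, the other 7 lost the call in at least 1, and the S phase list turned direction without naive WT 2 (adjusted p = 0.671). The myeloid and erythroid calls were lost without naive KO 2 (adjusted p = 0.313 and 0.451), where these markers were low.

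The plasma cell and ER lists were lower in iGCB KO cells, with medians of -0.92 and -0.81 (adjusted p = 0.163 and 0.222 with an estimated correlation). Dilution of the B cells by feeder or other cells would lower B cell genes alike, but the B cell receptor list without Cd79a had a median of 0.12 (21 members, quartiles -0.05 and 0.25), and fibroblast markers had a median of -0.07, although NK markers (1.27) and myeloid markers (0.38, adjusted p = 0.0509) had medians above 0 at summed levels of at most 42.4 and 168 CPM. If a bias of GC content or gene length lowered the ER list, it would also lower other genes like its members. However, 537 genes outside the lists that match the ER genes in GC content, length and expression had a median of 0.01 (quartiles -0.14 and 0.15). The plasma cell list was not matched in this way. A linear fit on GC content and length held 0.07% of the variance and left the ER median at -0.8, which decides nothing by itself. A smaller share of plasmablast-like cells in the KO cultures and lower expression in each cell after the loss of Pcbp1 cannot be told apart, since the counts come from pooled cells and 0 members of the plasma cell list were higher past the threshold.

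H2-Q genes were lower in KO cells at both stages, with H2-Q7 at -3.80 in naive and -2.48 in iGCB cells. Reads moved among class I paralogs would leave the class I total as it was, but the summed CPM of 20 class I genes was lower in KO by 1.37 on the log2 scale in naive cells (3854 ± 794 to 1496 ± 188 CPM) and had a log2 ratio of -0.8 in iGCB cells (3025 ± 495 to 1740 ± 134 CPM). This total also holds H2-K1 (-1.29 in naive and -0.81 in iGCB cells) and H2-D1 (-1.16 and -0.95), so it does not measure the H2-Q genes alone. A haplotype difference between the KO and WT mice around the H2-Q genes cannot be told apart from an effect of the loss of Pcbp1. Genes within 5 Mb with an unadjusted p under 0.05 and one sign at both stages were 4 of 213, against 220 of 19924 elsewhere (odds ratio 1.71, 95% interval 0.46 to 4.52, Fisher's exact p = 0.305). The strain of the mice is not given, and fewer mapped reads from a divergent allele would lower the class I total as well.

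Some genes of naive B cells were higher in iGCB KO cells, among them Ighd and Bank1. Naive cells carried over into the KO cultures with their day 0 expression would raise all abundant naive transcripts by one share. However, the 55 genes that were high in naive cells and at least 30-fold lower in iGCB WT implied a median share of 0.06% (quartiles -0.21 and 1.54), with 23 genes below 0. Carried-over cells whose expression changed over the culture are not covered by this test. Without the immediate early genes, an exclusion that was intended but left out of the written prediction, the 49 remaining genes also gave 0.06% (quartiles -0.35 and 1.46). Ighd alone would need a share of 9.19% and Bank1 7.44%. Why these genes were higher stays open, and no biological explanation was tested.

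The iGCB comparison gave 72 genes higher and 194 lower, and the highest counts in the other 9 of the 10 splits of its 6 libraries were 0 and 0 (edgeR), so 1 split was as large in either direction, the real one. These splits are too few for a share under 0.05.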

How the results depend on the processing

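The sex term, the fit without the 2 female naive libraries, counts divided by 2, thinned counts, and DESeq2 on only the groups compared were chosen after the data were seen. Pcbp1 was lower in KO at both stages under every alternative run. In iGCB cells it stayed past the threshold in each, from -6.89 to -6.42 when 1 library was left out. In naive cells, where it missed the threshold, it passed with DESeq2 (-5.62), no low-count filter (-5.57), the replicate block (-6.01), the sex term (-6.02), without the female libraries (-7.55), with counts divided by 2 (-5.56) and with counts thinned to the smallest library (-5.77), and it ran from -8.05 to -4.77 when 1 library was left out. The cause was not tested. Of the other comparisons of a single result with an alternative, 6959 stayed on the same side of the threshold, 284 passed it newly and 384 lost it. Another 9 changed direction with a call in the main fit or the alternative. A result called in neither fit was counted as the same even where its direction changed.

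Counts of genes higher and lower in naive KO cells were 115 and 65 with DESeq2, 126 and 116 with no low-count filter, 15 and 16 with the replicate block, 35 and 22 with the sex term and 7 and 16 without the female libraries, and limma-voom gave 10 higher. DESeq2 called all 3 higher and all 7 lower genes of edgeR. A fit of only the 4 naive libraries by edgeR gave 0 and 0 (348 at an unadjusted p under 0.05). Leaving out 1 library gave 2 to 17 higher and 9 to 27 lower, where a lone library is assumed to vary like the other groups. For iGCB cells the counts were 321 and 502 with DESeq2, 290 and 551 with no low-count filter, 329 and 534 with only the groups compared, 550 and 796 with DESeq2 on those groups, 212 and 377 with the replicate block, 221 and 419 with the sex term and 243 and 448 without the female libraries. DESeq2 called all 72 and 194 genes of edgeR. Without immunoglobulin and mitochondrially encoded genes they were 45 and 75, and without 1 library 12 to 52 and 26 to 145. The main fit shares each gene's spread over both stages. Naive replicates were less alike (Pearson r 0.9342 to 0.9383) than iGCB replicates (0.9794 to 0.9826). Fits of only the groups compared called more iGCB genes and fewer naive genes than the main fit. With 1 mean per group, naive libraries enter the iGCB contrast only through the filter, the scaling and the shared spread. RLE factors moved the iGCB counts little (73 and 207), and so did the stricter filter (86 and 218). With no low-count filter they were 290 and 551, so the filter and the shared spread were not told apart. Whether the shared spread accounts for the fewer naive genes was not tested either.

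In WT cells the replicate block gave 4219 genes lower in iGCB, and leaving out 1 library 4080 to 5013 higher and 5008 to 6224 lower. For the difference of the KO effects the counts higher and lower were 65 and 173 with DESeq2, 115 and 258 with no low-count filter, 19 and 55 with the replicate block, 21 and 87 with the sex term, 31 and 71 without the female libraries and 0 and 0 without immunoglobulin and mitochondrially encoded genes (edgeR, 1106 at an unadjusted p under 0.05). Limma-voom gave 1 higher, and leaving out 1 library 0 to 20 and 0 to 53. The Pearson r of the KO effects between stages was 0.032 with DESeq2, 0.026 with no low-count filter, 0.111 with the stricter filter, 0.206 with only the groups compared, 0.087 with limma-voom, 0.02 without the female libraries, 0.081 with counts divided by 2 and 0.206 over genes with a mean log2 CPM of at least 4, and 0.028 to 0.062 without 1 library. The cause was not tested.

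The number of lists called depended on the test. By fry, the ER and plasma cell lists (adjusted p = 0.0097 each) and the naive follicular list (0.0177) were called in iGCB KO. For the difference, fry called the plasma cell and naive follicular lists (adjusted p = 0.0335 each) but not the ER list (0.119). With an estimated correlation the number called was 0 in naive KO, 0 in iGCB KO, 0 in WT and 0 for the difference, and with fry 0, 3, 39 and 2. In naive KO it was 4 with the stricter filter and 3 without the female libraries. Leaving out 1 library gave 0 to 23 lists in naive KO, 10 to 17 in iGCB KO, 32 to 33 in WT and 7 to 21 for the difference. Lists that reversed in naive KO, with their range of adjusted p when 1 library was left out, were mitochondrial ribosome (0.0195 without WT 1, range 0.000512 to 0.154), G2/M (0.000102 without WT 1, range 4.54e-06 to 0.0651) and interferon (1 without WT 1, range 1.21e-11 to 1). Others were S phase (0.000744 without WT 2 and 0.0372 without KO 1, range 0.000744 to 0.154), immunoglobulin constant (0.0187 without WT 2, range 0.00347 to 0.405) and myeloid (0.883 without KO 2, range 4.41e-11 to 0.883). For the difference they were S phase (0.671 without naive WT 2, range 8.25e-08 to 0.671) and G2/M (0.044 without naive WT 2, range 2.97e-08 to 0.376). The cause was not tested.

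Scaling by library size alone moved the median log2 fold change of all genes from -0.048 to 0.074 in naive KO and from 0.035 to -0.102 for the difference, so small naive list medians depend on the scaling. Thinning all libraries to the smallest, 33400672 counts, kept the counts of genes in each comparison within 1.5 times.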

Other observations

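Xist, which is expressed from the inactive X chromosome, was at 1546 CPM in naive WT 1 and 1827 CPM in naive KO 1, where Ddx3y on the Y chromosome was at 0 CPM. In the other 8 libraries Ddx3y was at 116 to 168 CPM and Xist at 0 to 2.40 CPM. The labels do not give the sex of the mice. The 2 feeder ligand genes, too few to test as a list, had summed levels of 8.06, 9.58 and 2.17 CPM in iGCB WT and 7.47, 3.98 and 3.59 CPM in iGCB KO.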
